A study of Rattus norvegicus with 12 samples.

How the data were processed

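RNA from primary rat cortical neurons was measured on 12 two-colour Agilent arrays. Fetal brains came from 3 pregnant rats at pregnancy day 17, cells were kept apart by mother, and 4 plates were made per rat, per the labels. On day 16 in vitro, plates were exposed for 6 h in a gas-tight chamber to halothane at 1 or 3 MAC (about 1% or 3%) or to isoflurane at 3 MAC (about 4%), and were harvested after 6 h of recovery. MAC is the minimum alveolar concentration, the usual unit of potency of an inhaled anaesthetic. Control plates stood in the same incubator in air, outside the chamber, so a difference from control holds the time in the chamber as well as the gas. Each of the 4 groups has 3 arrays. The labels can be read as each rat giving 1 plate to every group, or as each rat giving 3 plates of 1 treatment and 1 control plate. Rats and treatments cannot be told apart under the second reading. The 3 arrays of a treatment would then be plates of 1 rat, and the 3 controls plates of 3 rats. The p-values measure a spread between plates pooled over all groups, which would then mix differences within and between rats.

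On every array the sample carried Cy5 and a pool of control RNA carried Cy3, per the labels. The deposited value of each spot is read here as the log10 ratio of Cy5 over Cy3, which is sample over pool. Base and direction are likely and not stated. The base rests on a limit at exactly 2 in the deposited values, a 100-fold ratio. The direction rests on the dyes and on the pool: over 134 features with a control SD above 1 on the log2 scale, the mean linear ratio of the 3 controls had a median of 1.06 (quartiles 0.99 to 1.19) when read as sample over pool and 1.48 (1.32 to 1.77) when read as pool over sample, where a pool of these controls would give 1. That arithmetic does not settle the base: with base 2 the same medians were 0.97 and 1.07. Read in the other direction every higher and lower would be exchanged, and with base 2 every log2 difference would be smaller by a factor of 3.32. All values were multiplied by 3.32, the log2 of 10, and are given as log2. Partek is named as software, per the submitters' processing notes, with no version. Background and dye correction on each array are not given in the sources used here. Spot intensities were not analysed here, so no probe could be judged against background, and the number of arrays limits the precision.

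The table held 21575 spots, of which 12750 (59.1%) had 1 gene symbol in the platform annotation, 5 had several and 8820 had none. Of the named probes, 12720 matched the RefSeq gene table and 0 were renamed, giving 9653 genes. An exact 0 stood in 15439 of the values (6.1%), against 1005 other values within 0.0005 of 0 on the log10 scale, and was treated as missing. The 471 spots that each stood at the 100-fold limit on at least 10 arrays, all unnamed, were left out. A gene with several probes was given the mean of its probes measured on all 12 arrays, or failing that the probe with most values. Unnamed probes stayed as features of their own. Features with values on at least 2 arrays of every group were tested, 16546 in all: 9210 genes and 7336 unnamed probes. No columns were left unused.

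Array medians lay between −0.005 and 0.005 on the log2 scale on 11 arrays and at 0.281 on halothane 1 MAC replicate 1. The SD over features of that array was 0.838, against 0.323 to 0.493 on the others. None of its 471 limit spots stood at the limit (0, against 467 to 471 on the others), and it held 330 exact zeros against 953 to 2124. It was kept, and each comparison was refitted without it.

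Groups were compared with limma 3.58.1 in R 4.3.3: lmFit over all 12 arrays with 4 group means, eBayes (8 residual and 3.46 prior degrees of freedom), two-sided moderated tests, Benjamini-Hochberg adjustment over the 16546 features and a threshold of 0.05. SE is the standard error from this fit, SD the spread of 3 arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9. The comparisons were each treatment against control, the halothane doses against each other, and halothane against isoflurane at 3 MAC.

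Comparisons, tests, 29 gene lists and 10 cell type lists, the alternatives and the rule for named genes were fixed before the data were examined, except where said. Of 1128 listed symbols, 882 were on the array. Lists were tested with camera (correlation preset at 0.01) over the 15919 features with values on all 12 arrays (8933 genes), adjusted over the 38 lists with at least 5 measured members. The red blood cell list had too few and was not tested. Each list was also tested with an estimated correlation and with fry, which asks whether its genes move on balance one way. List members were adjusted over all features and over the list alone. Named genes are the 8 largest changes in each direction past the threshold (5 between treatments) whose 3 treated values lay on one side of all 3 control values. Where fewer than 5 (3 between treatments) qualified, the genes of smallest p in that direction filled up to that number. Up to 4 members of smallest p per list were added. Symbols that only number a locus were passed over.

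Alternatives covered centring and scaling of arrays, missing values, the range filter, probes taken singly, the groups fitted, variance moderation, array weights, the pooled channel as the control, thresholds, a block by replicate number and each array left out in turn. Keeping exact zeros and the estimated correlation without halothane 1 MAC replicate 1 were added after the data were seen. The steps were tested on simulated data with 50 features changed at each size among 16546. For isoflurane against control the test recovered 16% of 1.5-fold, 36% of 2-fold, 94% of 4-fold and 100% of 8-fold changes, with 6 false calls. Over the 5 comparisons these shares were 6% to 16%, 36% to 54%, 86% to 96% and 94% to 100%, with 6 to 13 false calls (13 for halothane 3 MAC against control). The 2-fold share was 54% for halothane 1 MAC and 50% for halothane 3 MAC against control, 48% between the halothane doses and 50% between the agents. A list shifted by 0.4 on the log2 scale was called in all 5 comparisons, and 1 list that was not shifted was called as well, for isoflurane against control. Simulated genes varied independently of each other, so these runs do not show how the list test behaves where genes are correlated. Each simulated feature also had the same spread on every array. Differences in these shares between the 5 comparisons therefore come from the draw, and recovery where arrays or groups differ in spread was not tested.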

Results

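Gene expression was compared in primary cortical neurons from fetal rats after a 6 h exposure to an inhaled anaesthetic and 6 h of recovery. The 4 groups were untreated control, halothane at 1 MAC, halothane at 3 MAC and isoflurane at 3 MAC, with 3 arrays each. Halothane is a halogenated alkane and isoflurane a halogenated ether, and both are volatile general anaesthetics. There was no isoflurane group at 1 MAC. Every value is a log2 ratio, in the likely direction of a sample over one pool of control RNA, and treatments were compared through the 3 individual control arrays hybridised against the same pool. The opposite direction would exchange higher and lower throughout, and a log base below the 10 assumed for the deposited values would make every fold smaller.

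Across the 8933 named genes with values on all arrays, the 3 halothane 3 MAC arrays correlated with each other at r = 0.76 to 0.84 and the 3 isoflurane arrays at 0.64 to 0.74. Halothane 1 MAC replicates 2 and 3 correlated at 0.76, whereas replicate 1 reached at most 0.18 with any array. The controls did not resemble each other to that degree. Control 2 correlated with the halothane 3 MAC arrays at a mean of 0.76, but at 0.07 with control 1 and −0.05 with control 3. Control 3 correlated at a mean of 0.55 with the isoflurane arrays and at 0.42 with control 1, and control 1 at 0.61 with halothane 1 MAC replicates 2 and 3. These correlations are across genes, which are not independent replicates.

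**Figure D1:**
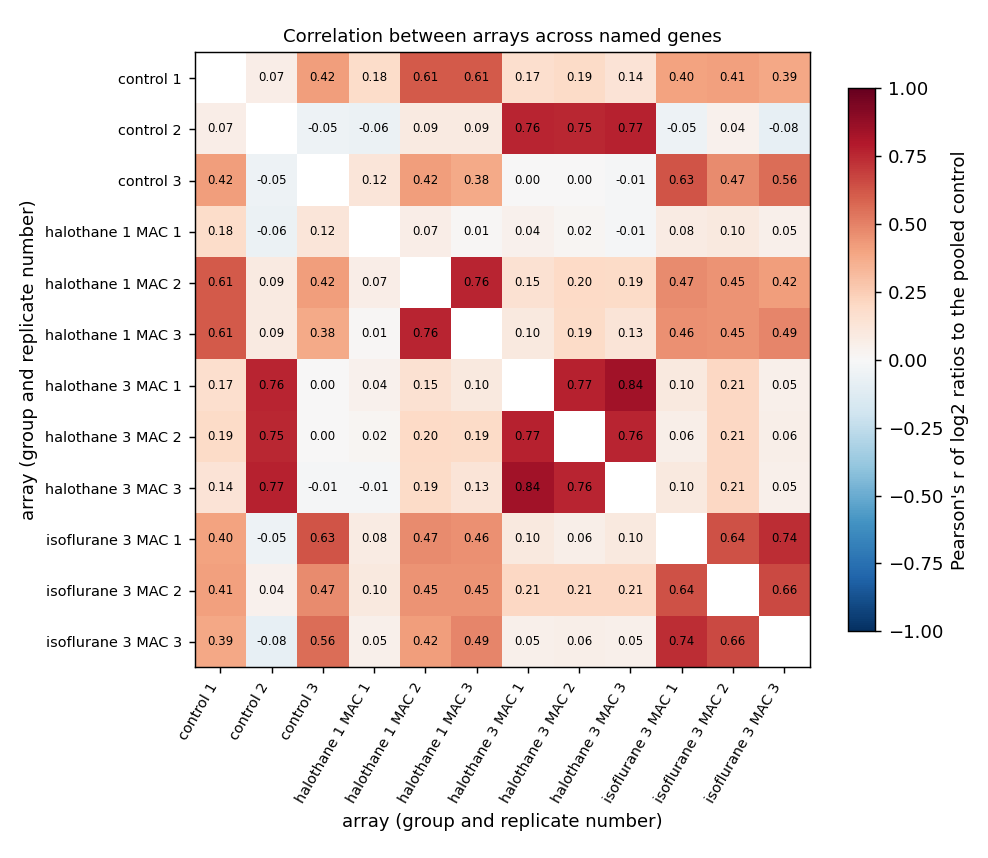
Pearson's r between every pair of the 12 arrays across 8933 named genes, from log2 ratios to the pooled control, with arrays labelled by group and replicate number on both axes. Control 2 lies with the halothane 3 MAC arrays (0.75 to 0.77), and halothane 1 MAC replicate 1 correlates with no array above 0.18.

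The isoflurane comparison asks what a clinical ether anaesthetic does to neuronal transcripts. Lingo2, a leucine-rich repeat membrane protein of neurons, fell by 1.56 ± 0.12 on the log2 scale with isoflurane (SE, 3 arrays against 3; 2.95-fold; adjusted p = 0.00054). Syt11, a synaptotagmin of vesicle traffic, rose 2.60-fold (1.38 ± 0.15, adjusted p = 0.0104). Neither passed with halothane. Lingo2 averaged −0.80 ± 0.02 (SD, n = 3) with halothane 1 MAC, −0.20 ± 0.10 with halothane 3 MAC, −1.53 ± 0.06 with isoflurane and 0.03 ± 0.07 in controls. The other genes that rose with isoflurane were the cytochrome P450 Cyp4b1 (2.33 ± 0.31, 5.02-fold), the secreted phosphoprotein osteopontin Spp1 (2.21 ± 0.34, 4.63-fold), the serine palmitoyltransferase subunit Sptssb (1.62 ± 0.24), the TGF-beta target Pmepa1 (1.32 ± 0.18), Tmem150a (1.23 ± 0.19) and the tyrosine kinase Tec (1.09 ± 0.15). Sh2d3c, a signalling adaptor with an SH2 domain, fell by 0.87 ± 0.13. Adjusted p of these 7 lay between 0.0303 and 0.0483, and the 2 probes of Sptssb gave 0.86 and 2.37. Ssbp2 (−0.75, adjusted p = 0.0798), the sialyltransferase St6galnac3 (−0.72, 0.0867) and the dopamine receptor Drd2 (−1.10, 0.116) came next below control and did not pass.

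**Figure D2:**
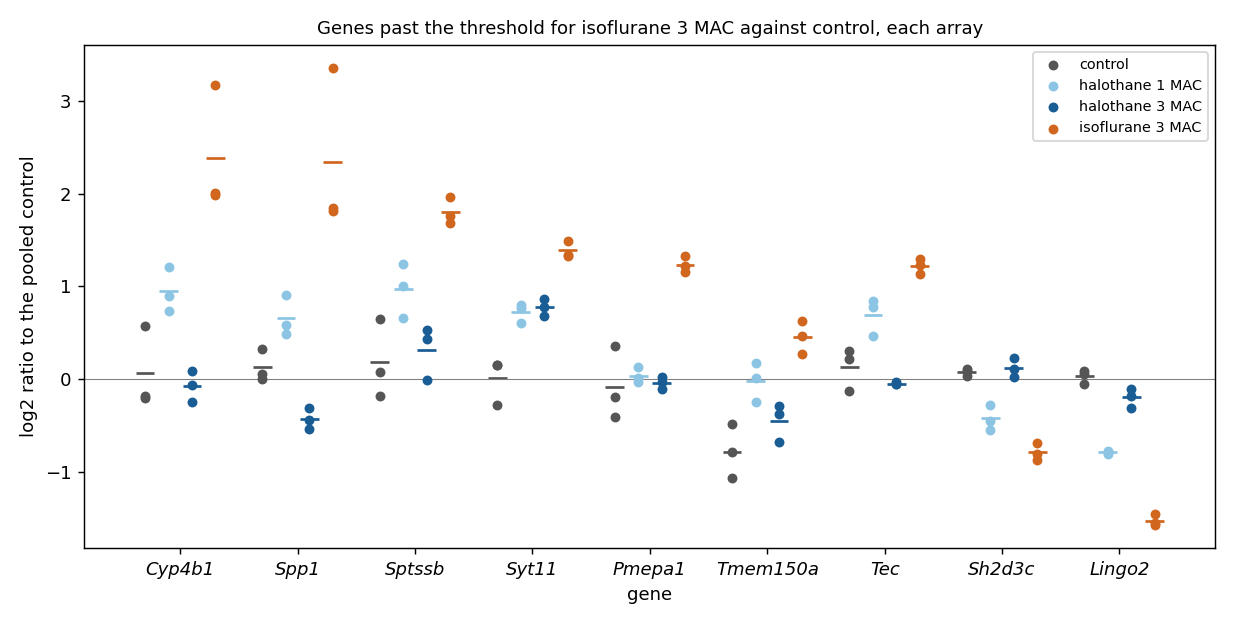
Log2 ratio to the pooled control (vertical axis) of the 9 genes past the threshold for isoflurane 3 MAC against control (horizontal axis), 1 point per array coloured by group, with a line at each group's mean of 3 arrays. All 3 isoflurane points lie outside the control range for each gene, and Lingo2 averages −1.53 with isoflurane and 0.03 in controls.

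In all, 12 of 16546 features passed between isoflurane and control, 10 higher and 2 lower, among them 9 named genes (7 higher, 2 lower). At an unadjusted p under 0.05 there were 1677 features, where chance would give 827. Lingo2 passed with any of the 12 arrays left out (adjusted p 0.000116 to 0.0101), Syt11 in all but the fits without isoflurane replicate 1 or 3 (up to 0.0798), and the other 7 genes in 2 or 3 of 12 fits. The count was 386 without halothane 1 MAC replicate 1, including all 12 features, 79 without control 3, and 5 without control 2, of which 2 were among the 12. It lay between 1 and 6 with any other array left out. Quantile normalisation gave 1 higher and 3 lower features, and scaling arrays to one median absolute deviation gave 6 higher and 3 lower. With the replicate number as a block 1 feature passed, which was among the 12.

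Genes of endoplasmic reticulum and oxidative stress were higher with isoflurane. The unfolded protein response list rose (20 genes, median 0.40, 18 above 0, adjusted p = 5.21e-07), as did amino acid response and ATF4 targets (26 genes, median 0.42, 25 above 0, 1.58e-07), NRF2 and oxidative stress genes (25 genes, median 0.31, 21 above 0, 3.78e-06) and metallothioneins with zinc and copper handling genes (11 genes, median 0.40, 10 above 0, 0.00132). With an estimated correlation the adjusted p-values were 0.209, 0.25, 0.209 and 0.209, so none of the 4 calls held. The lists passed with each of the 12 arrays left out. No member of these lists passed over all features, against 6, 3, 4 and 2 members higher when adjusted over the list alone. Among them were the disulfide isomerase Pdia4 (0.74 ± 0.14, adjusted p = 0.00309 over the list alone), the co-chaperone Dnajc3 (1.27 ± 0.25, 0.00309), the secreted glycoprotein Stc2 (1.34 ± 0.24, 0.0039), the cystine transporter Slc7a11 (1.49 ± 0.41, 0.0336), the quinone reductase Nqo1 (1.74 ± 0.28, 0.00149), the haem oxygenase Hmox1 (1.87 ± 0.56, 0.0413) and the metallothionein Mt1 (1.68 ± 0.38, 0.0102).

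The size of these shifts depended on the control array taken as reference, although every isoflurane array lay above every control array for all 4 lists. Isoflurane exceeded controls 1, 2 and 3 by 0.48, 0.69 and 0.41 for the unfolded protein response, by 0.33, 1.05 and 0.25 for ATF4 targets, by 0.36, 0.77 and 0.29 for NRF2 genes and by 0.37, 0.93 and 0.36 for metallothioneins. Control 2, which correlated with the halothane 3 MAC arrays, was the lowest of the 3 controls in each.

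Cholesterol biosynthesis and uptake genes fell with isoflurane: 1 of 23 lay above 0, and the median was −0.67 (adjusted p = 2.05e-13, but 0.217 with an estimated correlation). Adjusted over the list alone 12 were lower, and 0 over all features. The sterol pathway enzymes Nsdhl (−0.69 ± 0.15), Fdps (−1.02 ± 0.26) and Mvd (−1.35 ± 0.34) had the smallest p (0.0157 each over the list alone), and Acat2, which makes acetoacetyl-CoA, stood at −1.28 ± 0.36 (0.0243). The list mean differed from controls 1, 2 and 3 by −0.35, −1.16 and −0.45, and the list passed with each array left out.

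Markers of inhibitory neurons were lower (14 genes, median −0.30, 5 above 0, adjusted p = 0.0338, 0.217 with an estimated correlation), with 4 members lower when adjusted over the list alone: the GABA-synthesising enzyme Gad1 (−1.01 ± 0.25), the vesicular GABA transporter Slc32a1 (−0.75 ± 0.22) and the neuropeptide genes Tac1 (−0.65 ± 0.19) and Sst (−0.71 ± 0.24). This call was lost without control 1 (adjusted p = 0.0795), isoflurane replicate 2 (0.115) or halothane 1 MAC replicate 1 (0.099). Of the 14 markers, 8 are also members of another list. Neurotrophic factors and receptors were higher (27 genes, median 0.19, 19 above 0, adjusted p = 0.049, 0.209 with an estimated correlation), led by the growth factor Nrg1 (1.11 ± 0.21) and the sorting receptor Sort1 (0.79 ± 0.17), 2 members past the test over the list alone, and the call held in 3 of 12 fits with an array left out (without control 1, halothane 3 MAC replicate 1 or isoflurane replicate 2) and was lost in the other 9 (up to 0.164).

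Cytosolic ribosomal protein genes were slightly higher with isoflurane (46 genes, median 0.19, 39 above 0, adjusted p = 4.85e-04, 0.682 with an estimated correlation), with 0 members past the test even over the list alone. Rpl41 had the smallest p (0.79 ± 0.20), and the call was lost without control 3 (0.111). Cell cycle genes were lower (27 genes, median −0.22, 6 above 0, adjusted p = 0.0338, 0.739 with an estimated correlation), also with 0 members past: the DNA replication factor Mcm5 stood at −1.0 ± 0.33 and Pcna, another, at 0.56 ± 0.18. Without control 2 the direction of the cell cycle list turned upward (0.939), and the call was also lost without halothane 1 MAC replicate 1 (0.123) and isoflurane replicates 1 (0.155) and 3 (0.244). In all, 9 of 38 lists passed with the preset correlation and 4 with fry (the unfolded protein response, NRF2, metallothionein and neurotrophic lists).

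**Figure D3:**
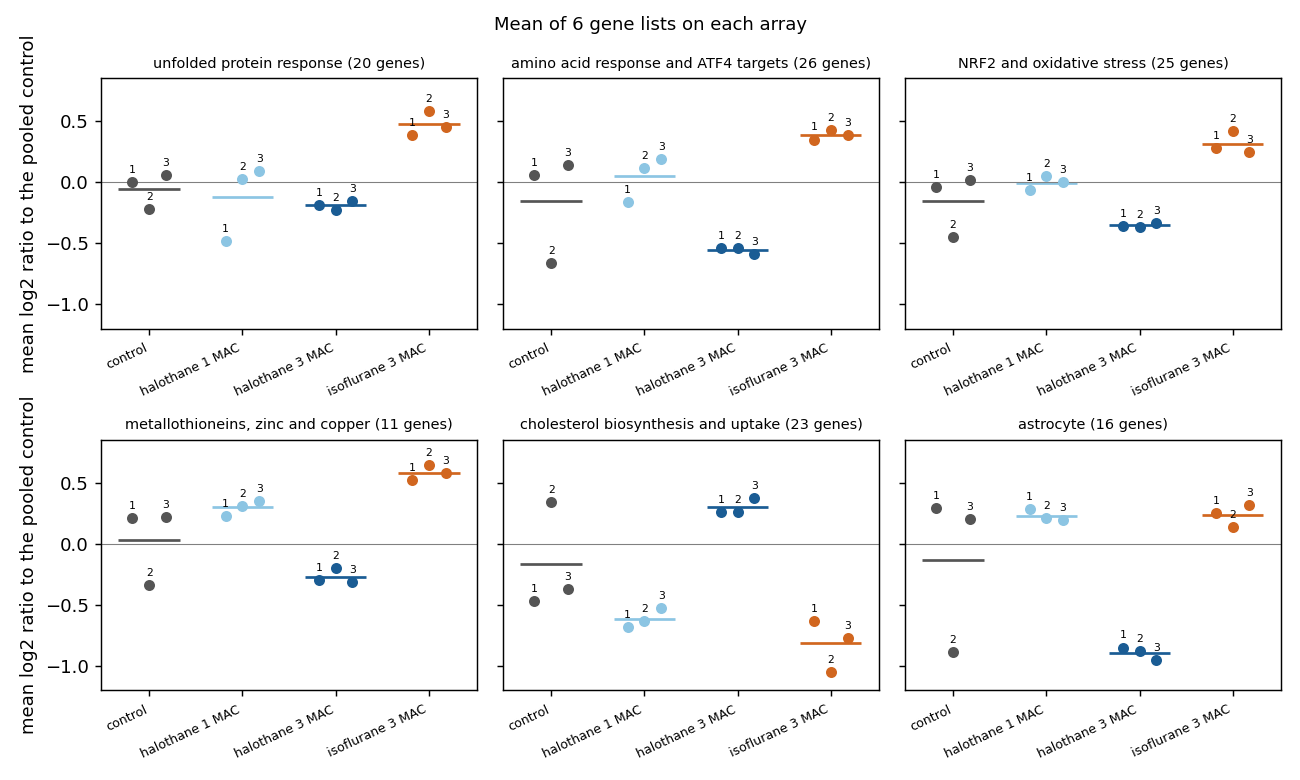
Mean log2 ratio to the pooled control (vertical axis) over the members of 6 gene lists on each of the 12 arrays, grouped by treatment (horizontal axis), with points numbered by replicate and a line at each group's mean. Control 2 lies at −0.89 for astrocyte genes and 0.34 for cholesterol genes, beside the halothane 3 MAC arrays (−0.95 to −0.85 and 0.26 to 0.37) and apart from controls 1 and 3.

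At 3 MAC of halothane, no gene passed against control (0 of 16546 features with limma, smallest adjusted p = 0.694), with 1090 at an unadjusted p under 0.05 where chance would give 827. The genes of smallest p above control were Syt11 (0.77 ± 0.15), Tdrkh (0.89 ± 0.18), the arginase Arg2 (0.69 ± 0.14), the transcription factor subunit Nfyb (0.63 ± 0.13) and the kinetochore gene Cenpk (0.98 ± 0.22). Those below control were Mypn (−0.94 ± 0.15), the phagocytic receptor Mertk (−1.02 ± 0.22), the potassium channel partner Kcnip2 (−0.71 ± 0.16), the arginine transporter Slc7a1 (−1.05 ± 0.24) and Rnase4 (−1.45 ± 0.34). The count depended on control 2: without it 465 features passed, and with any other array left out 0 did. Without moderated variances 1 feature passed, and with arrays weighted by their fit 724 did. The weights changed all arrays at once (0.05 for halothane 1 MAC replicate 1, 0.43 for control 2, 0.60 for control 3), so that count cannot be put down to control 2.

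Astrocyte markers were lower with 3 MAC halothane (16 genes, median −0.70, adjusted p = 1.46e-09, 0.352 with an estimated correlation), with 6 members lower over the list alone and 0 over all features. The intermediate filament gene Gfap stood at −1.98 ± 0.47, the matrix protein Sparcl1 at −1.43 ± 0.39, the water channel Aqp4 at −0.78 ± 0.23 and the secreted chaperone Clu at −1.16 ± 0.36 (0.0212 to 0.0298 over the list alone). Gfap read −2.37 ± 0.20 (SD, n = 3) on the halothane 3 MAC arrays, −1.91 on control 2, 0.38 on control 1 and 0.35 on control 3. The list lay −1.18 and −1.09 from controls 1 and 3 but −0.01 from control 2.

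Cell cycle genes were higher (26 of 27 above 0, median 0.52, adjusted p = 4.36e-11, 0.352 with an estimated correlation), with 0 members past over the list alone. The mitotic kinase Plk1 (1.08 ± 0.33), the spindle motor Kif11 (1.72 ± 0.55), the mitotic ubiquitin enzyme Ube2c (1.46 ± 0.47) and the replication factor Mcm6 (0.88 ± 0.30, 2 probes at 0.05 and 0.88) each reached 0.0648. Control 2 moved with this group as well, the list lying 0.92, 0.09 and 1.10 above controls 1, 2 and 3. Kif11 read 1.26 on control 2, against −0.95 and −1.30 on the other controls and 1.39 ± 0.02 with halothane 3 MAC.

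Cholesterol genes were higher with 3 MAC halothane (20 of 23 above 0, median 0.51, adjusted p = 3.05e-09, 0.509 with an estimated correlation), with 0 members past over the list alone, Idi1 at 1.00 ± 0.31 and Hsd17b7 at 0.83 ± 0.28. Immediate early genes, which respond to neuronal activity, were lower (22 genes, median −0.47, adjusted p = 5.49e-06, 0.352 with an estimated correlation), also with 0 members past, Junb at −1.13 ± 0.30 and Atf3 at −1.49 ± 0.52. ATF4 targets were lower (26 genes, median −0.20, adjusted p = 3.75e-05, 0.547 with an estimated correlation), with 4 lower over the list alone, among them Slc7a1, Slc7a11 (−1.52 ± 0.41) and the pseudokinase Trib3 (−2.34 ± 0.66). These 3 lists differed from controls 1 and 3 by 0.77 and 0.67, −0.69 and −0.64, and −0.61 and −0.70, and from control 2 by −0.04, 0.01 and 0.10.

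The other lists that passed were genes of mitochondrial oxidative phosphorylation (39 genes, median 0.16, adjusted p = 5.49e-04, 0.568 with an estimated correlation), xenobiotic metabolism (27 genes, −0.17, 0.00218, 0.547), calcium stores and calcium binding (20 genes, −0.18, 0.00665, 0.352), inflammatory and cytokine genes (33 genes, −0.06, 0.0141, 0.568), the interferon response (14 genes, −0.25, 0.0212, 0.568) and ribosomal proteins (46 genes, 0.12, 0.0334, 0.641). Here the values are list size, median, adjusted p and adjusted p with an estimated correlation. From controls 1, 2 and 3 the list means differed by 0.17, 0.06 and 0.21 for oxidative phosphorylation, −0.49, 0.03 and −0.54 for xenobiotic and −0.26, −0.06 and −0.29 for calcium genes. They differed by −0.11, −0.05 and −0.32 for inflammatory genes, −0.40, 0.07 and −0.43 for interferon genes and −0.03, 0.11 and 0.21 for ribosomal proteins. The inflammatory call was lost without control 3 (0.0959) or halothane 1 MAC replicate 1 (0.0539), and the interferon call without control 1 (0.104), control 3 (0.163) or halothane 3 MAC replicate 1 (0.0658). The ribosomal call was lost without control 2 (0.236), control 3 (0.421) or halothane 3 MAC replicates 1 (0.112) and 3 (0.0644). In all, 11 of 38 lists passed with the preset correlation, 0 with an estimated one and 0 with fry.

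At 1 MAC of halothane the cholesterol list was again lower than control: 2 of 23 genes lay above 0, and the median was −0.57 (adjusted p = 1.2e-09, 0.808 with an estimated correlation), and the list passed with each array left out. All 3 halothane 1 MAC arrays lay below all 3 controls, with differences of −0.14, −0.96 and −0.25 from controls 1, 2 and 3. Nsdhl (−0.61 ± 0.15) was the single member past over the list alone (0.0466), and Insig1 (−0.80 ± 0.27), Pmvk (−0.71 ± 0.24) and Fdps (−0.67 ± 0.26) did not pass. Genes of oxidative phosphorylation were lower (39 genes, median −0.18, 8 above 0, adjusted p = 1.65e-04, 0.808 with an estimated correlation), with 0 members past over the list alone, Ndufb5 at −0.45 ± 0.17 and Ndufa9 at −0.41 ± 0.19. That call was lost without halothane 1 MAC replicate 1 (0.282), and 2 of 38 lists passed in all (0 with fry).

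No gene passed between 1 MAC halothane and control (0 of 16546 with limma, smallest adjusted p = 0.275), with 1247 at an unadjusted p under 0.05 where chance would give 827. The genes of smallest p were Lingo2 (−0.82 ± 0.12), Cstf3 (−0.78 ± 0.17), the transporter Slco1b2 (−0.60 ± 0.14) and Anks1b (−0.79 ± 0.19) below control, and the complement regulator Cr1l (0.86 ± 0.15), the tryptophan-degrading enzyme Ido1 (0.88 ± 0.18), Syt11 (0.72 ± 0.15), the integrin Itga4 (0.74 ± 0.16) and the adenylyl cyclase Adcy8 (0.88 ± 0.20) above it. The count was 4 without control 1, 2 without moderated variances and 4 with array weights. Anks1b turned to 0.19 when set against the pooled channel in place of the control arrays. The median of all features stood 0.08 above control, and the array median of halothane 1 MAC replicate 1 was 0.281.

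The 2 halothane doses were compared to ask how the response depends on dose. Cholesterol genes were higher at 3 than at 1 MAC (23 genes, median 0.85, adjusted p = 1.32e-15, 0.517 with an estimated correlation), with 18 members higher over the list alone. Insig1, the sterol-regulated retention factor, differed by 1.45 ± 0.27, Nsdhl by 0.83 ± 0.15 and the isomerase Idi1 by 1.63 ± 0.31 (0.00165 each over the list alone). Astrocyte markers were lower at 3 MAC (16 genes, median −1.34, adjusted p = 2.16e-06, 0.522 with an estimated correlation; 11 lower and 1 higher over the list alone), Gfap by −2.66 ± 0.47 and the matrix protein Sparc by −1.68 ± 0.30. Immediate early genes were lower (22 genes, median −0.71, 1.04e-05, 0.517; 7 lower), Junb by −1.63 ± 0.30 and Fosl1 by −1.04 ± 0.23. The list means of the 2 doses differed by 0.91, −1.12 and −0.70 for cholesterol, astrocyte and immediate early genes, and the widest differences between 2 controls were 0.81, 1.17 and 0.69. Control 2 lay at the level of 3 MAC, at 0.34, −0.89 and −0.56 against 0.30, −0.89 and −0.55.

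Between the doses, ATF4 targets were lower at 3 MAC (26 genes, median −0.45, adjusted p = 3.57e-04, 0.642 with an estimated correlation; 11 lower and 1 higher over the list alone), with Slc7a11 at −2.15 ± 0.41 and the stress gene Ddit4 the other way at 1.05 ± 0.18. Cell cycle genes were higher (27 genes, median 0.43, 1.15e-04, 0.642; 4 past), including the proliferation marker Mki67 at 3.20 ± 0.83. The list means differed by −0.61 and 0.58 between the doses and by up to 0.80 and 1.00 between controls, with control 2 at −0.66 and 0.44 beside 3 MAC (−0.56 and 0.54). Oxidative phosphorylation (39 genes, median 0.40, 9.93e-08, 0.522) and cytoskeleton and axon growth genes (34 genes, 0.20, 0.0225, 0.517) were higher, and interferon (14 genes, −0.55, 0.00754, 0.522), xenobiotic (27 genes, −0.39, 0.0154, 0.642) and inflammatory genes (33 genes, −0.35, 0.0195, 0.685) lower at 3 MAC. In that order the list means differed by 0.29, 0.13, −0.57, −0.53 and −0.34 between the doses, and by up to 0.15, 0.18, 0.51, 0.56 and 0.26 between controls. The lowest control stood at −0.37 for interferon and −0.38 for xenobiotic genes, below the 3 MAC means of −0.29 and −0.36. The cytoskeleton call was lost without halothane 1 MAC replicates 2 or 3 or halothane 3 MAC replicate 2 (up to 0.0616) and the inflammatory call without halothane 1 MAC replicate 1 (0.237). Of the 10 lists past the test, none held with an estimated correlation and 5 passed with fry, as did nicotinic and related channels (lower at 3 MAC, adjusted p = 0.0222 with fry), which did not pass with the preset correlation (0.206).

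No single gene passed between the doses (0 of 16546 with limma, smallest adjusted p = 0.0607, 3067 at an unadjusted p under 0.05). The genes of smallest p were Ddit4, Kctd8 (1.80 ± 0.33) and Insig1 higher at 3 MAC, and Mertk (−1.64 ± 0.22), the protease Ctsh (−1.36 ± 0.21) and Pdlim4 (−2.09 ± 0.33) lower. The count was 698 without control 2, 69 without halothane 1 MAC replicate 1 and 15 without control 1, and 4209 with array weights. At the features with an unadjusted p under 0.05, control 2 differed from control 1 in the direction of the dose difference for 86.7%.

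Halothane and isoflurane were compared at the same multiple of MAC and the same times, and 580 features differed, 171 higher and 409 lower with halothane, among them 360 named genes (109 higher, 251 lower). The largest differences above were Ttr, a thyroid hormone carrier (4.14 ± 0.81, 17.7-fold), the cadherin Cdhr1 (3.34 ± 0.68), Eomes, a transcription factor of cortical intermediate progenitors (2.62 ± 0.63), the neuropeptide precursor Pmch (2.60 ± 0.53) and the replication factor Pclaf (2.53 ± 0.54). Those below were Ifi27l2b (−5.37 ± 0.86, 41.2-fold), Trib3 (−4.07 ± 0.66, 16.8-fold), the hyaluronan receptor Cd44 (−3.63 ± 0.60), Hmox1 (−3.56 ± 0.56, 2 probes at −4.29 and −2.83) and the galectin Lgals3 (−3.47 ± 0.48). Their adjusted p lay between 0.0116 and 0.045.

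The controls spread about as widely as the agents at Ttr, Cdhr1, Eomes, Pmch, Pclaf and Ifi27l2b. Ttr read 1.22 ± 0.46 (SD, n = 3) with halothane and −2.92 ± 0.64 with isoflurane, and −1.34, 1.28 and −2.95 on controls 1, 2 and 3. Ifi27l2b read −3.24 ± 0.06 and 2.13 ± 0.56, and 0.45, −3.62 and 0.76 on the controls. At Trib3, Cd44, Hmox1 and Lgals3 control 2 read −2.37, −2.01, −2.21 and −1.27, beside halothane means of −2.60, −1.84, −2.12 and −1.49. Isoflurane means of these genes were 1.47, 1.79, 1.43 and 1.98, above all 3 controls. Of the 575 features of the 580 with values on both arrays, 97.7% differed between controls 2 and 3 in the direction in which halothane differed from isoflurane.

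Cholesterol genes were higher with halothane than with isoflurane (23 genes, median 1.26, adjusted p = 2.33e-19, 0.118 with an estimated correlation), with 14 members higher over all features and 19 over the list alone. Mvd differed by 2.19 ± 0.34 (4.57-fold, adjusted p = 0.0156) and Acat2 by 2.13 ± 0.36 (4.39-fold, 0.0176). Cell cycle genes were higher too (27 genes, median 0.74, 3.08e-10, 0.179 with an estimated correlation; 4 and 15 members), with Mcm5 at 1.92 ± 0.33 and Mcm6 at 1.56 ± 0.30 (2 probes at 0.22 and 1.56). On control 2 the cholesterol list averaged 0.34 and the cell cycle list 0.44, against −0.37 and −0.56 on control 3.

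Stress genes were lower with halothane than with isoflurane. No unfolded protein response gene lay above 0 (0 of 20, median −0.56, adjusted p = 1.18e-07, 0.118 with an estimated correlation), with 4 lower over all features and 9 over the list alone, among them Pdia4 (−0.82 ± 0.14), Dnajc3 (−1.41 ± 0.25) and the chaperone Hspa5 (−1.15 ± 0.28). ATF4 targets (26 genes, median −0.61, 1.29e-11, 0.118; 7 and 14 lower), NRF2 genes (25 genes, −0.32, 4.46e-05, 0.118; 6 and 11 lower) and metallothioneins (11 genes, −0.70, 8.92e-04, 0.118; 3 and 5 lower) followed, with Slc7a11 at −3.01 ± 0.41, Nqo1 at −1.97 ± 0.28 and Mt1 at −2.47 ± 0.38. Control 2 averaged −0.22, −0.66, −0.45 and −0.34 for these 4 lists, below both other controls in each.

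Astrocyte markers were lower with halothane (16 genes, median −1.07, adjusted p = 1.18e-07, 0.21 with an estimated correlation), with 6 lower and 1 higher over all features and 10 and 1 over the list alone. Gfap differed by −2.94 ± 0.47 (7.66-fold) and the intermediate filament gene Vim by −1.70 ± 0.30, and 3 of the 16 markers, Mt1 among them, are members of another list. Immediate early genes (22 genes, median −0.79, 7.34e-05, 0.212; 5 and 10 lower) included Ccn1 at −2.62 ± 0.36, and inflammatory genes (33 genes, −0.29, 0.00117, 0.408; 3 and 7 lower) included the chemokine Ccl2 at −3.41 ± 0.51. Xenobiotic metabolism (27 genes, −0.28, 0.00165, 0.343), calcium stores (20 genes, −0.31, 0.00912, 0.144), neurotrophic factors (27 genes, −0.25, 0.0117, 0.118), microglia and macrophage markers (14 genes, −0.58, 0.0135, 0.583) and the interferon response (14 genes, −0.53, 0.0248, 0.435) were lower and cytoskeleton genes higher (34 genes, 0.24, 0.0168, 0.179). The microglia call was lost without isoflurane replicate 1 (0.233), the cytoskeleton call without isoflurane replicate 2 (0.0607) and the interferon call without control 3, halothane 3 MAC replicate 1 or isoflurane replicate 1 (up to 0.107). In all, 15 lists passed with the preset correlation and 0 with an estimated one. With fry 11 of the 15 passed, and so did hypoxia and glycolysis genes (lower with halothane, 0.0256), which did not pass with the preset correlation (0.37).

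The lists of anaesthetic targets did not pass between the agents. The difference of the list means, halothane minus isoflurane, was −0.13 for GABA-A and glycine receptor subunits (95% interval −0.26 to 0.01), −0.03 for glutamate receptors (−0.35 to 0.29), −0.02 for 2-pore and voltage-gated potassium channels (−0.16 to 0.12), 0.01 for sodium, calcium and HCN channels (−0.16 to 0.18) and −0.01 for nicotinic and related channels (−0.16 to 0.14). For synaptic vesicle genes it was −0.13 (−0.34 to 0.08), for postsynaptic genes −0.06 (−0.26 to 0.15) and for excitatory neuron markers 0.00 (−0.20 to 0.19). Against control these lists did not pass with either agent. The SE behind each interval was shared by all comparisons, so it also holds the spread of groups not compared. For glutamate receptors the list mean had an SD of 0.38 at halothane 1 MAC, against 0.06 at halothane 3 MAC and 0.08 with isoflurane.

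The count between the agents fell whenever a halothane 3 MAC or isoflurane array was left out, a fit that leaves 2 arrays in that group. It was 0, 1 and 1 without halothane 3 MAC replicates 1, 2 and 3 and 32, 61 and 6 without isoflurane replicates 1, 2 and 3, but 2047 without halothane 1 MAC replicate 1 and 1038 without control 2, both including all 580, and 794 without control 3. It was 22 without moderated variances, 2807 with only these 6 arrays and 4390 with array weights, and quantile normalisation gave 243 higher and 357 lower.

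Changes from control were also set against each other across 15919 features. Those with halothane 3 MAC and with isoflurane correlated at r = −0.09, where unchanged groups sharing the same controls gave a mean of 0.666 over 100 simulations, and their covariance was −0.0086 against 0.0312, a difference of −0.0398. Halothane at 1 and 3 MAC correlated at −0.07 against 0.432, with a covariance of −0.0067 against 0.0311 and a difference of −0.0377. Over all features tested the correlations were −0.067 and −0.05, and without control 2 both were above 0, at 0.214 and 0.259. The 3 controls cannot be split with 2 arrays on each side, so part of each value may come from the shared controls. Simulated controls were independent of the treatments, whereas control 2 followed halothane 3 MAC (mean r = 0.76) and control 3 isoflurane (0.55). The simulated values are therefore no fair reference for these arrays, and opposite responses cannot be concluded.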

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

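The tests of a shared culture or batch and of exchanged arrays were chosen only after the result was seen, and the test of the replicate number before it. Because the difference between treatments was itself tested, 3 results stood out: the 580 features and 15 gene lists that separated halothane from isoflurane at 3 MAC, and the 10 lists that separated halothane at 3 MAC from 1 MAC. With an estimated correlation none of the 15 or the 10 lists passed (adjusted p at least 0.118 and 0.517). Of the 10 ways to split the 6 arrays, too few for a share under 0.05, 1 gave as many features between the agents as the real 580 (highest other 0) and 2 as many lists as the real 15 (highest other 17). Between the halothane doses 1 split gave as many lists as the real 10 (highest other 6).

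The same test set apart 10 named genes between halothane and isoflurane at 3 MAC. The log2 differences above 0, halothane minus isoflurane, were 4.14 for Ttr, 3.34 for Cdhr1, 2.62 for Eomes, 2.60 for Pmch and 2.53 for Pclaf. Those below 0 were −5.37 for Ifi27l2b, −4.07 for Trib3, −3.63 for Cd44, −3.56 for Hmox1 and −3.47 for Lgals3. Each lost its call whenever a halothane 3 MAC array or isoflurane replicate 3 was left out. All but Lgals3 lost it without isoflurane replicate 1, and all but Lgals3 and Pclaf without replicate 2. Eomes lost it in 9 of 12 fits (adjusted p with limma up to 0.159), also without control 1 or halothane 1 MAC replicates 2 or 3. The differences kept their direction over the 12 fits (Ttr 3.91 to 4.51, Eomes 2.42 to 2.97, Pclaf 2.24 to 3.06, Ifi27l2b −5.55 to −5.04, Trib3 −4.22 to −3.86, Cd44 −3.92 to −3.15).

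Features that separated the agents also separated control plates, 97.7% of 575 in the same direction between controls 2 and 3 (control 3 minus control 2 against halothane minus isoflurane gave r = −0.93 and a slope of −0.75) and 91.2% of 580 between controls 2 and 1. Each halothane 3 MAC array correlated better with the other 2 than with controls 1 and 3 by at least 0.67. That argues against an exchange with control 2 only if the true control would resemble controls 1 and 3, which themselves correlated at 0.42. Control 2 correlated with halothane 3 MAC replicates 1 and 3 at 0.76 and 0.77, and replicate 2 did so at 0.77 and 0.76. Where cultures or batches differ, an exchange of control 2 with replicate 2 therefore cannot be judged. With or without that exchange, an unexposed plate correlated at 0.76 or 0.77 with halothane 3 MAC replicates 1 and 3. The replicate number as a mark of the culture is argued against, with a correlation of deviations between same-numbered arrays as low as −0.08. Each control correlated best with a different treatment group. The means were 0.61 for control 1 with halothane 1 MAC replicates 2 and 3, 0.76 for control 2 with halothane 3 MAC and 0.55 for control 3 with isoflurane. That each control shares a culture, litter or array batch with 1 treatment group remains a candidate explanation. Differences from the 3 controls together would then mix culture with agent. A direct effect of the agents, which the design names, would not by itself separate plates that were not exposed. Over the 575 features the 97.7% in the same direction and the slope of −0.75 therefore argue against the agents as the whole cause. That rests on 1 array of each control, and an agent effect as a part of the difference stays open and untested. The labels allow a reading in which rats and treatments coincide, and neither rat nor scan date is given per array.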

How the results depend on the processing

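Keeping exact zeros and the estimated correlation on 11 arrays were chosen only after the data were seen. Signal over background was not analysed here, so its limit is unknown. Every list past the test kept its direction under the alternatives other than left-out arrays. Among named genes, 1351 values under other settings kept direction and side of the threshold, 153 newly passed, 78 no longer passed and 1 reversed (Anks1b at 1 MAC, 0.19 against the pooled channel); with arrays left out the counts were 1130, 65 and 209. Where no construction is named the cause was not tested.

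For isoflurane against control, where 12 features passed, the counts were 4 with quantile normalisation, 7 with no filter on missing values, 7 with robust moderation, 346 with array weights, 2346 against the pooled channel (which leaves out the controls' own spread), 1 with only the 2 groups compared, and 1 and 75 at thresholds of 0.01 and 0.1. For halothane 3 MAC against control, from 0, they were 1 with variances not moderated, 724 with array weights and 1426 against the pooled channel. For halothane 1 MAC, from 0, they were 1 with quantile normalisation, 1 with scaled arrays, 2 with variances not moderated, 4 with array weights and 725 against the pooled channel. Between halothane doses, from 0, they were 150 with quantile normalisation, 7 with scaled arrays, 275 with features above the median range (fewer features), 297 with only the 2 groups, 4 with variances not moderated, 4209 with array weights and 582 at 0.1. Between agents, from 580, they were 2807 with only the 2 groups, 22 with variances not moderated, 4390 with array weights, and 1 and 1114 at 0.01 and 0.1.

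Lists past the test numbered 0 in all 5 comparisons with an estimated correlation, on 12 and on 11 arrays. With fry they were 0 for both halothane doses, 4 for isoflurane and 6 between doses, of which 5 were among the 10. For halothane 1 MAC, from 2, they were 4 with scaled arrays, 4 with each probe by itself, 1 with features above the median range and 8 with array weights.

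With each array left out in turn, features ranged over 0 to 4 for halothane 1 MAC, 0 to 465 for halothane 3 MAC, 1 to 386 for isoflurane, 0 to 698 between doses and 0 to 2047 between agents. Lists ranged over 2 to 7, 8 to 12, 6 to 11, 9 to 12 and 13 to 17 in that order. The correlation of halothane doses ranged from −0.107 to 0.259 (jackknife SE 0.31) and that of the agents from −0.124 to 0.214 (0.272). Without control 2 both turned from below 0 (−0.05 and −0.067) to above it, at 0.259 and 0.214, and without control 1 the former stood at 0.089. Quantile normalisation gave 0.026 and 0.013. A fit that leaves a group with 2 arrays assumes the common spread.

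The replicate numbers did not pair the arrays: 15 correlations of deviations between same-numbered arrays, without halothane 1 MAC replicate 1, lay between −0.08 and 0.09, and 5 of 12 arrays matched best with an array of their own number in another group. With the number as a block, isoflurane had 1 feature and the agents 431, of which 401 were among the 580. As a random block its consensus correlation was −0.014.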

Other observations

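The comparison of any exposure with control and the tests of the chamber, of astrocytes and of another RNA were chosen only after the results were seen. Lists of cell stress other than those named above did not pass between isoflurane and control: heat shock proteins and chaperones had a median of 0.02 (24 genes, adjusted p = 0.62), hypoxia and glycolysis genes 0.09 (27 genes, 0.649), p53 targets and apoptosis genes 0.16 (28 genes, 0.204) and proteasome subunits 0.02 (26 genes, 0.772). All 3 isoflurane arrays nonetheless lay above all 3 controls for the heat shock, hypoxia and p53 lists, whose means differed by 0.09 (95% interval −0.06 to 0.23), 0.11 (−0.02 to 0.24) and 0.17 (0 to 0.34). With halothane at 3 MAC the same lists stood at −0.05, −0.03, 0.05 and 0.09 (adjusted p 0.59, 0.391, 0.487 and 0.205). The difference of list means, halothane minus isoflurane, was −0.16 for heat shock genes (−0.31 to −0.01) and −0.20 for hypoxia genes (−0.33 to −0.07), and neither list passed between the agents with camera (0.473 and 0.37), whereas hypoxia genes passed with fry (0.0256; heat shock genes 0.0596). Clock genes had a median of −0.01 with either agent at 3 MAC, but their list means differed by −0.25, halothane minus isoflurane (−0.46 to −0.04; adjusted p = 0.37). With halothane at 1 MAC the median was 0.22 (14 genes, 12 above 0, adjusted p = 0.295).

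Markers of other cells did not pass against control with any treatment, apart from those of astrocytes and inhibitory neurons. Median changes with isoflurane were 0.34 for microglia and macrophages (14 genes, adjusted p = 0.126), 0.20 for the oligodendrocyte lineage (11 genes, 0.34), 0.05 for endothelial and mural cells (16 genes, 0.987), 0.04 for fibroblasts (13 genes, 0.932) and 0.13 for neural progenitors (13 genes, 0.209). General neuron markers stood at −0.09 with isoflurane, 0.01 with halothane at 3 MAC and −0.15 at 1 MAC (12 genes, adjusted p 0.66, 0.391 and 0.112). Genes regulated by neuronal activity and those of GABA synthesis and transport stood at 0.08 and 0.04 with isoflurane (25 and 9 genes, 0.587 and 0.774).

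Genes of the unfolded protein response, ATF4, NRF2 and metallothionein lists were higher with isoflurane than with halothane at 3 MAC, although both gases were given in the chamber. These 4 calls were lost with an estimated correlation (adjusted p = 0.118 each). For 4 of 4 lists the difference between the agents (0.66, 0.95, 0.67 and 0.85) exceeded the widest difference between 2 controls (0.28, 0.80, 0.47 and 0.57). That argues against time in the chamber as the whole cause only if the plates of the 2 agents shared a culture and batch. Whether they did is not known, so these values cannot settle it. More astrocytes on the isoflurane plates were examined next. Over controls 1 and 3 the astrocyte list fell short of the 4 lists, at −0.05 ± 0.12 (SE over 16 members) against at least 0.33 and 0.04 ± 0.12 against 0.25. That SE measures the spread of genes and not of plates, and each value rests on 1 control array. The shortfall therefore does not settle whether astrocytes differed from the plates of controls 1 and 3. Against the halothane arrays and control 2 the astrocyte list differed by more than the smallest of the 4 lists, by 1.13 ± 0.25 against 0.66 and 1.12 ± 0.24 against 0.69, so a difference in astrocytes remains a candidate explanation there. An effect of isoflurane itself stays open and untested, and a shared culture or batch, which the design may confound with treatment (97.7% of features above), remains open.

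Halothane 1 MAC replicate 1 stood apart from the other 11 arrays. Its slope on the other 2 arrays of its group was at most 0.25 of the slope between those 2 (0.20 and 0.03, against 0.78 and 0.74). This cannot settle whether values were deposited before background and dye correction, on top of the same biology, since background left in can compress ratios and lower a slope. Compression alone would not widen the ratios, which were spread more widely than on any other array (SD 0.838 against 0.323 to 0.493). What an uncorrected dye effect adds to that spread was not tested. Compression that varies with intensity was not tested. Its 0 spots at the limit, 330 exact zeros and median of 0.281 go with other processing as a part of the difference. Another RNA and a failed hybridisation cannot be told apart without spot intensities, and its highest correlation with any array was 0.18. No biological explanation was tested.

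Lingo2 and Syt11 lay outside the control range on all 9 exposed arrays. With all exposures together, Lingo2 was lower by −0.87 ± 0.10 (adjusted p = 0.0293) and Syt11 stood at 0.96 ± 0.12 (0.0536, not past the threshold). Across 15919 features, 78 lay above and 51 below all 3 controls on all 9 exposed arrays, where chance would give 72 each, and 558 had an unadjusted p under 0.05. The 1 feature past the threshold became 0 without control 2 and 6 without halothane 1 MAC replicate 1. Lists past the test were cholesterol genes, lower (5.63e-06, but 0.717 with an estimated correlation and, without control 2, turned upward at 0.925), ribosomal proteins, higher (0.0152, 0.845), and NRF2 genes, higher (0.0398, 0.717). The last 2 were each lost in 5 of 12 fits with an array left out, ribosomal proteins at 0.102 without control 2 and 0.533 without control 3 and NRF2 genes at 0.974 without control 2. With halothane at 3 MAC the cholesterol list had a median of 0.51 above control, a call lost with an estimated correlation. Its mean lay 0.77 and 0.67 above controls 1 and 3 but −0.04 from control 2. A fall against controls 1 and 3 was therefore not common to all exposures. Chance was not excluded: of 100 splits drawn from 220, 6 gave at least 1 feature (highest other 454) and 74 at least 3 lists (highest other 16). The split with 454, which set control 2 and halothane 3 MAC replicates 1 and 3 against the rest, points to a structure of the samples.

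For the comparisons with control and between the doses, the 10 splits of 6 arrays are too few for a share under 0.05. At 1 MAC halothane all 10 gave at least the real 0 features (highest other 3) and 10 at least the real 2 lists (highest other 8). At 3 MAC halothane 10 gave at least 0 features (highest other 0) and 2 at least the real 11 lists (highest other 14). With isoflurane 2 gave at least the real 12 features (highest other 12, with isoflurane replicate 2 in place of control 3) and 7 at least the real 9 lists (highest other 15). Between the halothane doses 10 gave at least the real 0 features (highest other 0).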
